A study of Mus musculus with 2 samples.

How the data were processed

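RNA bound by an antibody was sequenced from mouse forebrain, the front part of the brain that holds the cortex and hippocampus. BG4 is an antibody that binds G-quadruplexes, the stacked structures that guanine-rich RNA or DNA can fold into. In RNA immunoprecipitation followed by sequencing (RIP-seq), RNA that stays on the antibody is eluted and made into a library. Normal rabbit IgG, which has no chosen target, took the place of BG4 in the control. There were 2 libraries, 1 with BG4 and 1 with IgG, both made with an Ion Torrent total RNA kit, per the labels' protocols. The groups were taken from the antibody label of each sample.

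The authors deposited 1 table of 170 genes with a value per gene in each library. Per the submitters' processing notes, Cufflinks was used and the genome build was mm10. The version of Cufflinks, the aligner, the gene annotation and the way strand was handled in counting are not given in the sources used here. The column layout is that of the gene table written by Cuffdiff, a program of the Cufflinks package. The deposited values were therefore taken to be FPKM (fragments scaled to transcript length and to the mapped fragments of the library), although the file header names no unit. The table also held the authors' log2 of each FPKM value, without a pseudocount, and these were not used beyond a check that they equal the log2 of the values. The deposited p-value and q-value of each gene come from the authors' comparison of the 2 libraries, per the file headers. With 1 library per antibody, such a test compares those libraries, not the antibodies.

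The table was a selection: each of the 170 genes was higher in BG4 and had a deposited p-value of at most 0.04865. The rule of selection is not given in the sources used here, and other genes were not analysed here. The number of reads in each library is unknown, because the values are FPKM with the gene lengths used by the authors not given. No counting interval or floor was computed. Library scaling between BG4 and IgG is not given either.

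For each gene, the log2 ratio was computed as the log2 of (BG4 + 1) over (IgG + 1), with a pseudocount of 1 FPKM. Such a ratio understates the difference of genes with low values. Genes needed at least 1 FPKM in 1 library or more, which all 170 met. Genes were counted above a fixed 2-fold ratio on this scale. No p-value or standard error was computed across the libraries, since there were no replicates.

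Genes were matched to GENCODE release M21, an annotation of the same build, by identifier without its version. All 170 identifiers matched, 11 of them with the version as well, and 163 symbols were equal to those of the annotation. Start positions in the table count from 0 (start plus 1 equalled the annotated start for 128 genes, the unshifted start for 2), so 1 was added to each. For 106 genes the deposited locus equalled the annotated gene at both ends. For the other 64 it did not, and some of these loci extended into neighbouring genes.

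Putative G-quadruplex motifs were searched on the longest annotated transcript as 4 runs of 3 or more guanines with loops of 1 to 7 bases. Loops could be of any base, guanine included, so 1 long stretch of guanines could count as more than 1 of the 4 runs. The mean number of motifs per kilobase in the 163 listed protein-coding genes was set against 10000 random sets of other protein-coding genes, drawn from 21788 genes in 10 bins of transcript length, with a 2-sided p. The smallest p that this number of sets can give is 0.0001. Coding parts and UTRs came from the annotation. Spearman's rho across genes was given a 2-sided permutation p from 100000 resamples and a 95% bootstrap interval from 10000 resamples. The 3 main relations were adjusted together by the Benjamini-Hochberg method, and so were the 9 alternative ones. Genes are not independent replicates. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used, with seed 1.

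The groups, tests, alternatives, 23 gene lists (779 genes) and the rule for the genes named were fixed before the data were examined, except for the alternatives and tests said to be chosen afterwards. The rule took the 15 highest and 10 lowest log2 ratios, the 10 highest BG4 values, every member of a list of published RNA G-quadruplex mRNAs, and up to 4 members of each other list. It gave 34 genes. A percentile of each list's median among random lists had been planned, for lists with at least 5 measured members. No list reached that number, so members were counted and described, except for 1 that is not reported here.

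The random gene sets were tested on simulated data for the comparison of listed with unlisted genes, over 21951 genes. Of 100 random lists, 6% had a p under 0.05. Of 100 lists drawn at double odds from the upper part of motif density, 89% did. A search for a common unit in the BG4 to IgG folds put 100% of 160 folds built on 1 unit on a grid, and 7.5% of 160 folds built without one. The number of tests behind the authors' q-values was recovered in 5 of 5 simulated tables of 170 genes. The alternatives tried were other pseudocounts, value filters and fold thresholds, division of each library by its median, other motif definitions, parts of the transcript and comparison genes, and median transcript properties.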

Results

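RNA bound by BG4, an antibody to G-quadruplexes, and RNA bound by normal rabbit IgG were sequenced from mouse forebrain, with 1 library each. The deposited table held 170 genes with a value in both libraries, taken to be FPKM from the layout of the table, 163 of them protein-coding. They lay on 20 chromosomes, with 6 genes on X and 0 on Y. The IgG values had a median of 0.143 FPKM (quartiles 0.0704 and 0.421), and 153 genes were under 1 FPKM. The BG4 values had a median of 7.88 FPKM (quartiles 5.32 and 14.3), and 70 genes reached 10 FPKM. There were no replicates, so none of the values below carries a spread between samples, and the read depth behind them is unknown.

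The first comparison asked which transcripts were recovered more with BG4 than with IgG. Nup54, a protein of the central channel of the nuclear pore, had a log2 ratio of 7.56, with 207 FPKM in BG4 and 0.103 in IgG. Wdr44, a WD-repeat protein that binds the small GTPase Rab11, stood at 7.31 (167 against 0.0621 FPKM). With the pseudocount of 1 FPKM Nup54 ranked highest, and with one of 0.1, or with none and Timm10b left out for an IgG value of effectively 0, Wdr44 did. Myo18a, an unconventional myosin, stood at 6.98 (185 against 0.478 FPKM). Kcnn4, a calcium-activated potassium channel, stood at 6.81 (210 against 0.882 FPKM), and Ncapd2, a subunit of condensin, at 6.50 (99.6 against 0.112 FPKM). The long non-coding transcript 4930500J02Rik had the highest BG4 value after Ccdc107, 350 FPKM against 1.99 in IgG, a log2 ratio of 6.87.

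In mm10, the deposited locus of Nup54 (ENSMUSG00000034826.10) was chromosome 5, 92415540 to 92435219, on the minus strand. Wdr44 (ENSMUSG00000036769.10) lay on chromosome X, 23693051 to 23806025, and Myo18a (ENSMUSG00000000631.15) on chromosome 11, 77763246 to 77865980, both on the plus strand. The locus of 4930500J02Rik (ENSMUSG00000086454.3) was chromosome 2, 104559163 to 104571429, and that of Kcnn4 (ENSMUSG00000054342.7) chromosome 7, 24370263 to 24385209, both on the plus strand. Ncapd2 (ENSMUSG00000038252.9) lay on chromosome 6, 125168007 to 125191701, on the minus strand, and its exons shared 237 bases with the small RNA gene Scarna10 on the same strand. In the authors' deposited table, q was 0.00662 for both Wdr44 and Myo18a, 0.0179 for 4930500J02Rik, Kcnn4 and Ncapd2, and 0.0818 for Nup54. That test compares the 2 libraries, not the antibodies.

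Ccdc107, a coiled-coil domain protein, had by far the highest value in both libraries, 179132 FPKM in BG4 and 1198 FPKM in IgG, a log2 ratio of 7.22. It made up 98.2% of the summed BG4 values and 94.99% of the summed IgG values of the table. Its BG4 value was 512 times that of the next gene, and its IgG value 328 times. The deposited locus of Ccdc107 (ENSMUSG00000028461.8) ran from 43492788 to 43495921 on chromosome 4, whereas the annotated gene began at 43492900 on the plus strand. The locus start equalled that of Rmrp, the RNA component of the RNase MRP ribozyme, annotated on the minus strand from 43492788 to 43493058. Exons of Ccdc107 and Rmrp shared 124 bases, all of them in the first exon of 1 of the 6 annotated Ccdc107 transcripts. Reads of the overlapping genes cannot be told apart without strand, and the values of Ccdc107 are uncertain for that reason. In the authors' deposited table, its q was 0.0818.

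**Figure D1:**
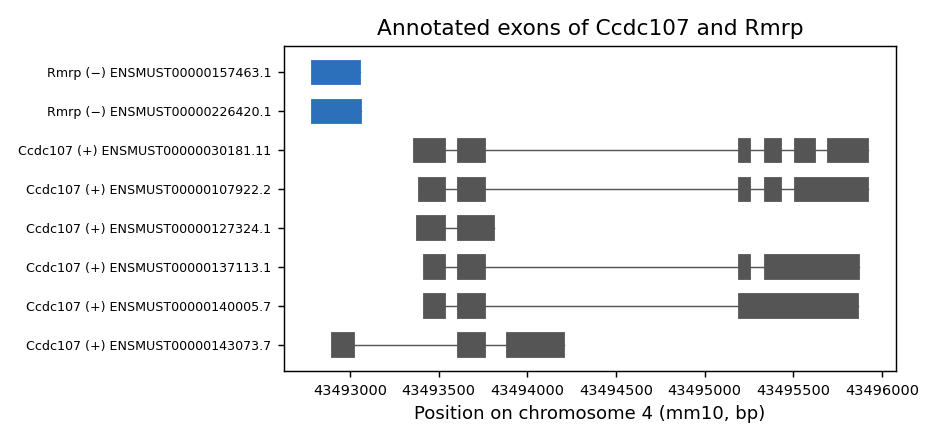
Annotated exons (boxes) of the Rmrp and Ccdc107 transcripts by position on chromosome 4 in mm10, in base pairs, with strand in brackets. One Ccdc107 transcript has its first exon, from 43492900 to 43493023, inside Rmrp, and the other Ccdc107 transcripts start downstream of it.

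The other genes among the 15 highest ratios with the pseudocount of 1 FPKM had log2 ratios from 4.69 to 6.03. Without a pseudocount and with Timm10b left out, 7 of the 15 genes were still among the 15 highest, and Itsn1 (45.5-fold) and Pfkfb3 (48.6-fold) lay below the median fold of the table, 54.2. Bzw2, a regulator of translation initiation, stood at 6.03 (67.4 against 0.0463 FPKM) and Ankrd42 at 5.52 (62.5 against 0.381 FPKM). Itsn1, a scaffold of endocytosis at synapses, stood at 4.98 with a higher IgG value, 100.5 against 2.21 FPKM. Prkag3, a regulatory subunit of AMP-activated protein kinase, also stood at 4.98 (36.5 against 0.190 FPKM), and Znrf2, a ubiquitin ligase, at 4.91 (30.9 against 0.0590 FPKM). Ankrd12, whose fold without a pseudocount equalled those of Fam114a2 and Mrpl42 to 5 digits, stood at 4.84. Erlin1, a protein of the endoplasmic reticulum, stood at 4.83, and Pfkfb3, a regulator of glycolysis, at 4.69. Among these genes, from Bzw2 to Pfkfb3, only Ankrd12 had an authors' q under 0.05 (0.0205). For the others, q ran from 0.0525 for Znrf2 and Pfkfb3 to 0.280 for Ankrd42. Of the 15 genes, 11 were under 1 FPKM in IgG. The non-coding Gm11523 was among the 10 highest BG4 values, 90.0 FPKM, but had 3.26 FPKM in IgG and a log2 ratio of 4.42.

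At the low end of the table, the 10 lowest log2 ratios with the pseudocount of 1 FPKM ran from 1.82 for Pqlc1 (4.95 against 0.689 FPKM) to 2.09 for Rundc3a (4.56 against 0.308 FPKM). Nsun5, an RNA methyltransferase of the ribosome, had the highest IgG value after Ccdc107, 3.65 FPKM, and 17.9 FPKM in BG4, a log2 ratio of 2.02. Kdm1a, a histone demethylase, stood at 1.89 (4.27 against 0.424 FPKM), Telo2 at 1.90 and Cspp1, a protein of centrosomes and cilia, at 1.93. Copz1, a coatomer subunit, stood at 1.95, Phf20 at 1.98, Sipa1l3 at 2.03, and Glrx2, a mitochondrial glutaredoxin, at 2.04.

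Exons of 57 listed genes overlapped those of another annotated gene, 13 of them on the same strand, and values of these genes are uncertain where reads could be shared. Among the named genes these were Ccdc107, Ncapd2, Ankrd42, Syt7, Rps18, Mir124-2hg, Brsk2, Cacna1h, Nsun5 and Cspp1. Itsn1 and Kdm1a had no such overlap, but their deposited loci reached beyond the annotated gene, so shared reads are not excluded for them. Across the table, the median log2 ratio was 2.87 (quartiles 2.44 and 3.58). The size depends on the pseudocount, because most IgG values were far below 1 FPKM: without one, the median was 5.76. The median fold without a pseudocount was 54.2, and it ran from 4.89 for Nsun5 to 2696 for Wdr44. Timm10b was left out of that range, because its IgG value of 2.49e-05 FPKM was effectively 0 and its fold has no meaning. In the authors' deposited table, q was from 0.00662 to 0.334 over the 170 genes and was under 0.05 for 14 of them.

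**Figure D2:**
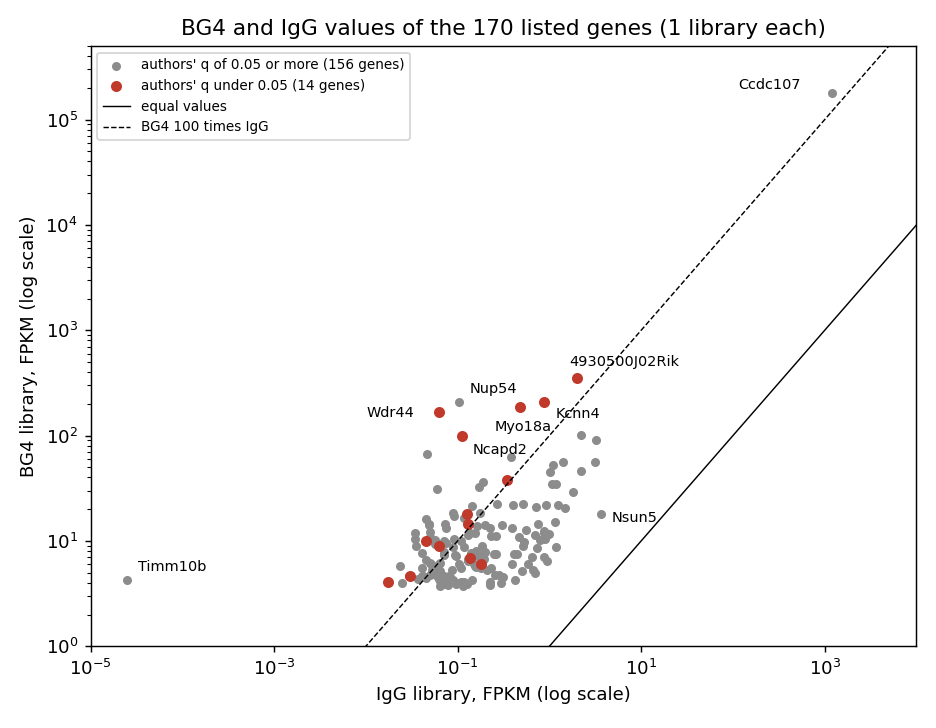
BG4 value against IgG value of each of the 170 listed genes, in FPKM on log axes, with 1 library each and lines for equal values and for BG4 at 100 times IgG. Each point lies above the line of equal values, red points are the 14 genes with a q under 0.05 in the authors' deposited table, and Ccdc107 stands apart at 179132 FPKM in BG4.

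The second comparison counted genes by size of the difference. All 170 genes, from Nup54 to Pqlc1, were above a 2-fold ratio of BG4 to IgG with the pseudocount of 1 FPKM, and 0 were below it in the other direction. Without a pseudocount and with Timm10b left out, 163 genes were at 10-fold or more and 54 at 100-fold or more. The table held only genes higher in BG4, so the count describes the selection as much as the libraries. Each library was also divided by its own median (7.88 FPKM for BG4, 0.143 FPKM for IgG), and 1 was then added to each quotient. On that scale 17 genes were above 2-fold and 29 lower by the same measure. The added 1 stands for 1 library median, an unlike amount of FPKM in the 2 libraries, and both counts depend on it.

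The third comparison asked whether gene groups of the forebrain were present. Of 779 genes on 23 preset lists, 8 were in the table. Each had a higher value in BG4, as all 170 genes did by the selection, so this direction says nothing about the lists. Syt7, a calcium sensor of the presynaptic terminal, had a log2 ratio of 3.67 (13.9 against 0.163 FPKM). Rps18, the member of the cytosolic ribosomal proteins, stood at 2.80 (9.66 against 0.527 FPKM). Mir124-2hg, a host transcript of the neuronal microRNA miR-124 and the member of the non-coding RNAs, stood at 2.57 (5.25 against 0.0531 FPKM). The kinases held 2 members, both kinases related to AMP-activated protein kinase: Brsk2 at 2.54 (5.17 against 0.0645 FPKM) and Mark2 at 2.45 (4.63 against 0.0302 FPKM).

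Ndufa7, a subunit of respiratory complex I and the member of nuclear oxidative phosphorylation, stood at 2.37 (4.38 against 0.0370 FPKM). Cacna1h, a T-type calcium channel and the member of the voltage-gated ion channels, stood at 2.34 (4.37 against 0.0625 FPKM). The authors' q was 0.0179 for Mark2 and 0.0525 for Brsk2. For the other list members described, it ran from 0.232 for Rps18 to 0.332 for Syt7. The published RNA G-quadruplex mRNAs had 0 of 39 genes in the table. The lists of GABA neurons, astrocytes, oligodendrocytes, microglia, endothelial and mural cells, choroid plexus with ependyma and meninges, and red blood cells had 0 members too. So did the lists of the cytoskeleton, the mitochondrial genome, glycolysis and housekeeping, RNA-binding and stress granule proteins, chromatin and transcription, immediate early genes, histones, and neurodegeneration and repeat-expansion genes. The lists do not cover whole classes: Kdm1a, a histone demethylase, and Myo18a, an unconventional myosin, were in the table but on none of the lists. Absence from the table gives no level, since the table is a selection. It held 163 protein-coding genes against 21788 others in the annotation, so lists of this size would have few or no members by the numbers alone.

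The fourth comparison asked whether transcripts of the listed genes hold more sequence that could fold into a G-quadruplex. Of the 163 protein-coding genes, 32 (19.6%) had at least 1 putative motif with runs of 3 or more guanines, 46 motifs in all. Of these, 23 lay in 3' UTRs, 14 in 5' UTRs, 4 in coding sequence and 5 in transcripts with no coding part annotated. Of the 15 genes with the highest ratios, 3 had a motif in their longest transcript, with 2 in Itsn1 and 1 each in Kcnn4 and Pfkfb3. The other 12, Nup54 and Wdr44 among them, had 0. Mark2 and Hal, the enzyme that breaks down histidine, had 4 each, and Syt7 had 3. Hal was chosen after its values were seen (3.95 FPKM in BG4 and 0.0990 in IgG).

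The first of the Syt7 motifs was GGGTGGAGGGGTGGGGGGG in the 3' UTR, at 10450641 to 10450659 on chromosome 19. In Mark2, on the same chromosome, GGGGGTCGGGGGGGGGGG lay in the 5' UTR at 7341435 to 7341452, and the other 3 motifs lay in the 3' UTR. In Itsn1, GGGGTGGGGGTAGGGTCAGGG lay in the 3' UTR at 91918045 to 91918065 on chromosome 16. In Brsk2, GGGTGTGGGGTGGGGCCGCTGGGG lay in the 3' UTR at 142003300 to 142003323 on chromosome 7. Rundc3a, among the 10 lowest ratios with the pseudocount of 1 FPKM, held GGGCCGGGGCGCCGGGTGGGG in its 5' UTR at 102393614 to 102393634 on chromosome 11. In Kcnn4, GGGGCAGGGGGCGGAGGGGGGG lay at 24386125 to 24386146 on chromosome 7, in a transcript with no coding part annotated and beyond the end of the deposited locus. The sequences shown for Syt7, Mark2 and Kcnn4 met the definition only because guanine within a longer stretch could serve as a loop.

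The listed genes had 0.0692 motifs per kilobase, against a mean of 0.0782 in random sets of the same transcript length (middle 95% of the sets 0.0518 to 0.108), a difference that did not pass the test (p = 0.532, n = 163 genes). Motifs with runs of 2 or more guanines were denser in the listed genes, 2.73 against 2.28 per kilobase (p = 0.0019, n = 163 genes), but with sets also matched on GC content the means were 2.73 and 2.71 (p = 0.9). The listed transcripts had a mean GC content of 50.7%, against 48.3% in the length-matched sets (n = 163 genes, p = 0.0001, the smallest that 10000 sets can give). Listed genes also had more annotated transcripts, a median of 9 against 3 in the other protein-coding genes. The sets for motifs and GC content were not matched on that number. Against genes of the preset lists that were not in the table, an alternative chosen after the data were seen, the density of motifs with 3 or more guanines was 0.516 times that of the random sets (p = 0.0004, n = 163 genes). These lists held the published RNA G-quadruplex mRNAs, a list chosen for such structures, and without it the density was 0.525 times (p = 0.0003, n = 163 genes). Random sets from the preset-list genes were themselves denser, 0.134 motifs per kilobase against 0.0782 from all other genes, and were not matched on GC content. The lower ratio thus depends on the choice of comparison genes.

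**Figure D3:**
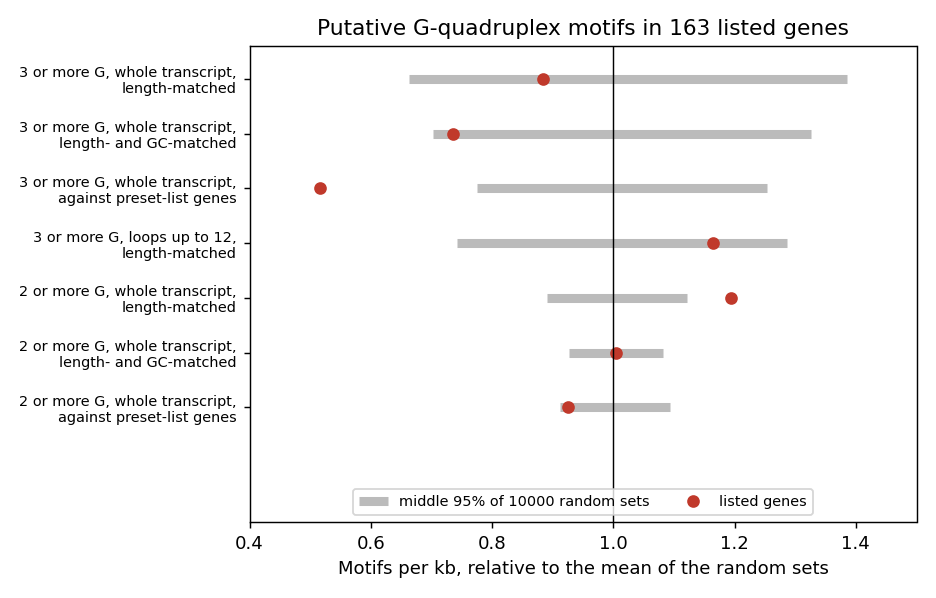
Putative G-quadruplex motifs per kilobase in the 163 listed protein-coding genes (points), relative to the mean of random gene sets, with the middle 95% of 10000 sets as bars, by motif definition and by what the sets were matched on. With 3 or more guanines the listed genes lie at 0.885 of the length-matched mean, and with 2 or more guanines they lie at 1.19 with length matched and at 1.005 with GC content matched too.

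The fifth comparison asked whether the ratio followed properties of the transcript across the 170 genes. Genes among the 15 highest ratios differed widely in length and GC content: the longest transcript of Wdr44 had 4167 bases and 40.1% GC, that of Myo18a 7513 bases and 57.7%, and that of 4930500J02Rik 770 bases and 43.6%. Itsn1 had 14012 bases and 50.8% GC. Across genes, Spearman's rho of the log2 ratio was -0.065 with length (permutation p = 0.401, adjusted p = 0.591), -0.065 with GC content (permutation p = 0.404, adjusted p = 0.591) and -0.042 with motifs per kilobase (permutation p = 0.591, adjusted p = 0.591). None of these 3 relations passed the test, within a table that held only genes higher in BG4. With the pseudocount of 1 FPKM, the ratio is close to a ranking by BG4 value where IgG values are far below 1 FPKM. Of the 10 highest BG4 values, 9 were among the 15 highest ratios. Without a pseudocount, rho with GC content was -0.233 (permutation p = 0.0023, adjusted p = 0.0207 over 9 alternative relations), so that genes of lower GC content had higher ratios on that scale.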

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

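Tests against the preset-list genes, with or without the published RNA G-quadruplex mRNAs, without exon overlap, without Ccdc107, of 2 or more guanines with GC content or the preset-list genes, and of the correlations without a pseudocount were chosen only after the data were seen. No paired analysis was possible because there was 1 library per antibody. Read depth is unknown, so how far depth limits the low IgG values could not be computed. With no replicates, a value counted as moved when it changed by over 1.5-fold.

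The median log2 ratio of 2.87 became 4.95 with a pseudocount of 0.1 and 5.76 with none. Of the 34 named genes, 29 moved under each of the 2 settings and 5 did not. Each kept its direction, which no pseudocount can turn for a gene higher in BG4. Of the 15 highest ratios, 12 were shared with a pseudocount of 0.1 and 7 with none, leaving out Timm10b, and of the 10 lowest, 6 were shared with each. The median of the 8 list members, 2.49, became 5.02 with a pseudocount of 0.1. Low IgG values cause these shifts by construction. The count of 170 genes above 2-fold became 70 with at least 10 FPKM required and 17, with 29 lower, after division by the library medians, which centres the table by construction. It was 170 with a pseudocount of 0.1 or no filter, neither of which can lower it, and 164 at 4-fold. List percentiles, also with length matched, gave no value.

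The motif density ratio of 0.885 (n = 163 genes) turned to 1.19 with 2 or more guanines (p = 0.0019), 1.16 with loops to 12 bases (p = 0.241), 1.37 in 3' UTRs (p = 0.254) and 1.005 with 2 or more guanines and GC content matched (p = 0.9). Against the preset-list genes it was 0.516 (p = 0.0004, n = 163 genes), and without the published RNA G-quadruplex mRNAs 0.525 (p = 0.0003, n = 163 genes). Random sets from the preset-list genes were themselves denser, with 0.134 motifs per kilobase against 0.0782 from all other genes. The other settings gave 0.598 to 0.926 and did not pass the test. The rank correlation of motif density with the ratio, -0.042, turned to 0.074 in 3' UTRs and 0.033 in coding sequence, with neither past the test (permutation p = 0.345 and p = 0.685). That of GC content with the ratio, -0.065, became -0.233 without a pseudocount (permutation p = 0.0023). For the motif and GC results the cause was not tested, except for the 2-guanine motifs. The rank correlation of length with the ratio stayed between -0.065 and -0.021.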

Other observations

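Of the tests in this part, that of bases shared with Rmrp, those of length bounds for Ccdc107, of median transcript length with IgG FPKM, of equal folds and of a grid of folds, and those of preset-list genes and of 2-guanine motifs with GC content matched were chosen only after the data were seen. The genes named in the next paragraph were chosen after their values were seen.

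Of the 14 genes with a q under 0.05 in the authors' deposited table, 7 fell outside the rule for named genes. Zfp280d, a zinc finger protein, had 18.1 FPKM in BG4 and 0.125 in IgG, and Dazap1, an RNA-binding protein, 14.4 and 0.131. Stxbp5, the syntaxin-binding protein tomosyn, had 10.02 FPKM in BG4 and 0.0448 in IgG, and Mettl17, a methyltransferase-like protein of mitochondria, 9.04 and 0.0626. Gtf2i, a general transcription factor, had 6.88 and 0.137 FPKM, Stx5a, a syntaxin of the Golgi, 5.99 and 0.178, and Il15ra, an interleukin receptor subunit, 4.08 and 0.0174. Dazap1 held 2 putative G-quadruplex motifs, GGGGCGCAGCGGGCCGGGACGGGG in the 5' UTR at 80265122 to 80265145 and GGGTTCGGGTGTGGGAAGCGGG in the 3' UTR at 80288117 to 80288138 on chromosome 10. Stxbp5 held 1, and Zfp280d, Gtf2i, Mettl17, Stx5a and Il15ra had 0 in their longest transcript. Exons of Zfp280d, Dazap1, Mettl17 and Stx5a overlapped those of another gene, so their values are uncertain in the same way.

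Ccdc107 held nearly all of the listed FPKM in both libraries. Division by a short transcript length did not account for this: multiplied by transcript length in kilobases, its BG4 value was still 119.839 times that of the highest other gene, and 46.2 times with its shortest annotated transcript of 363 bases. Reads of Rmrp counted for Ccdc107 remain a candidate explanation, since the exons share 124 bases and the value was also the highest with IgG. Rmrp lies on the opposite strand, and how strand was handled is not given in the sources used here. A biological explanation, that Ccdc107 RNA itself was bound by BG4, could bear only on the BG4 library, not on the highest value with IgG. For the BG4 value it was not tested and stays open.

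The table held only genes higher in BG4, with a lowest BG4 value of 3.76 FPKM. IgG values of the listed genes lay far below the BG4 values, a direction that the selection fixed and a size that it may have shaped. If they rested on about 1 read per gene, IgG FPKM should fall with transcript length, but Spearman's rho across genes was -0.00739 with the longest transcript (95% bootstrap interval -0.155 to 0.144) and -0.00568 with the median transcript length (-0.154 to 0.146). The folds, in which length cancels if it was the same for both libraries, did not lie on a grid either. At best 8.12% of 160 folds were whole multiples of 1 unit within 0.01, against 6.88% to 8.12% in 20 jittered sets. Exactly 1 IgG read per gene, counted whole, would give such a grid, but a few reads would not. The test by length rests on annotated lengths, and those used by the authors are not given. Neither test can therefore decide whether the IgG values rest on about 1 read. Ankrd12, Fam114a2 and Mrpl42 had the same fold of 109.22, and as many tied folds occurred in 0.2% of 1000 simulated sets, but their IgG FPKM times length in kilobases was 3.71, 0.108 and 0.235, where equal read numbers would give similar values, so the read numbers behind these genes stay open. The hypothesis that more motifs per kilobase give a higher ratio was neither borne out nor excluded, with rho at -0.0416 and an interval from -0.199 to 0.116.

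Motifs with 2 or more guanines per run were denser in the listed genes than in genes of matched length. Their GC content may account for this, since the ratio was 1.005 with GC content matched. Comparison genes that the forebrain does not express may account for it too, but this could not be decided. Against the preset-list genes, leaving out the published RNA G-quadruplex mRNAs, the ratio was 0.926. Those genes were not chosen by their expression or matched on GC content. Their random sets were also denser, 2.94 motifs per kilobase against 2.28 in those drawn from all other protein-coding genes. For motifs with 3 or more guanines, whose difference with length matched did not pass the test, the ratio with GC content matched was 0.735 (p = 0.0935, n = 163 genes), which leaves the role of GC content open. Binding of BG4 to such motifs was not tested directly.

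The authors' p and q fitted 4234 tests, with a whole rank within 0.01 for 122 of the 170 genes. At the authors' p of 0.001, 98 tests had a p at or below that value, of which 14 were listed genes and 84 were not, and 4.23 were expected with no difference. At the authors' p of 0.0482, the rank was 612, with 168 listed genes and 444 tests not listed, and 204 were expected with no difference. Of the listed protein-coding genes, 7 (4.29%) had exons overlapping a small RNA gene, against 2.39% in length-matched sets (p = 0.113, n = 163 genes) and 3.53% in sets also matched on the number of transcripts (p = 0.67, n = 163 genes).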
